A study of Mus musculus with 7 samples.

How the data were processed

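Stromal vascular cells of inguinal subcutaneous adipose tissue of female C57BL/6N mice, 4 young (11-12 weeks) and 3 old (18 months), were profiled by the authors with 10x Genomics 3' v3 single-cell RNA sequencing, after collagenase digestion, red blood cell lysis and a final passage through a 40 µm filter, per the labels' protocols. The deposited files hold, per library, a matrix of UMI counts with its barcodes and genes. The authors made these counts with Cell Ranger 4.0.0 on build mm10, per the submitters' processing notes. The deposited counts are whole numbers with at least 500 UMIs per barcode, and no annotation of cells was used here. Immunoglobulin and T cell receptor constant genes are not among the features.

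Cells were kept with at least 500 UMIs, at least 300 genes and at most 15% of UMIs from mitochondrial genes. Doublets were scored per library with Scrublet, and the highest scores were taken as doublets at a rate that grows with the number of barcodes (2.51% to 7.34% per library). They were left out after clustering. Counts were log-normalised with scanpy 1.11.5, and 2000 variable genes and 30 principal components gave a 15-neighbour graph for Leiden clustering (leidenalg 0.10.2) at resolution 1, without batch integration. This gave 49 clusters, of which 37 were named from markers fixed before the data were examined. The score limits for a name were set after the clusters and their libraries had been seen, and before any test between ages. The 12 unnamed clusters held 2254 of 37372 kept cells (6.37% of young and 5.84% of old cells on average), and 7 of them were mostly doublets. Cell class names are rebuilt from markers and stand for X-like cells. Progenitors were clustered again at resolution 1 into 19 sub-clusters.

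UMI counts were summed per library and class over libraries with at least 20 cells of the class. Old and young sums were compared with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest, 2-sided) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled counts of these sums. Unscaled CPM was used for Sp110, Atf3 and Cxcl1 and for the collagen genes of old replicate 3 set against the other libraries. It was also used for comparing folds of the C130026I21Rik family between classes. Numbers of cells per class were compared with edgeR quasi-likelihood on the kept cells of each library and with an exact permutation test of the mean logit share over the 35 splits, 2-sided, for classes with at least 20 cells. Gene lists fixed before the data were examined, with at least 5 tested members, were compared with limma 3.58.1 camera (preset correlation 0.01) on voom weights, adjusted over all lists and classes, beside camera with an estimated correlation and fry.

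Named genes per main class follow a rule fixed before the data were examined. It took the 10 largest increases and 10 largest decreases among genes that passed, did not overlap between ages, reached a mean of 20 CPM at 1 age and were not over 10 times higher in another class, leaving out Gm- and Rik-named models. It added up to 4 passing members of each list that passed (the 2 lowest p-values where none did), a fixed set of genes, and the 4 lowest p-values among genes left out for possible free RNA. Other classes took up to 2 genes per direction. Genes over 10 times higher in another class are counted per class as possible free RNA.

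The tests were run on simulated data with 200 changed genes per class. The gene counts of a class were drawn with 1 common dispersion and independent libraries. The recovery therefore does not cover differences in spread between genes or libraries that stand apart. At a log2 fold change of 2, edgeR recovered 95% of 100 changed genes in progenitors (14035 genes), 97% in macrophages, 95% in T cells, 98% in endothelial cells and 91% in B cells, and at a log2 fold change of 1 it recovered 30%, 25%, 18%, 34% and 24%. A simulated 8-fold higher neutrophil share was recovered in 31 of 50 draws over 16 classes.

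The alternatives were each library left out in turn, the replicate number as a block, RLE size factors, DESeq2 1.42.0, no expression filter and doublets kept. Further ones were stricter cell filters (at least 500 genes, at most 5% mitochondrial), clustering at resolution 2 and counts thinned to equal mean UMIs per cell. For shares, TMM factors and shares of cells other than lymphocytes were used too. Merging similar libraries and leaving out clusters of low UMI content were added after seeing the data. Pairs of libraries of the same age shared 4 to 13 barcodes, and their progenitor sums differed by a chi-square per degree of freedom of at least 18.2, so no library repeated another. Intervals are 95% exact Clopper-Pearson intervals, and a count of 0 is given the limit of 3 counts; both cover counting error only. Locations are from GENCODE release M21, in which all 165 named genes and 27722 of the 27998 gene identifiers were found.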

Results

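Gene expression was measured by 10x Genomics 3' v3 single-cell RNA sequencing of stromal vascular cells, the non-adipocyte cells of fat tissue, from inguinal subcutaneous adipose tissue of female C57BL/6N mice. The design compares 4 young mice (11-12 weeks old per the labels) with 3 old mice (18 months old). Each library is read as 1 mouse from the series' numbers, since the labels do not say whether a library pools mice. The deposited matrices held 45514 barcodes and 27998 genes. Total counts per library lay between 52336665 and 99516882 unique molecular identifiers (UMIs). After filtering, the young libraries kept 4493, 5581, 2797 and 5575 cells and the old libraries 6201, 6904 and 5821 cells. The old libraries were shallower per cell: the median kept cell held 9240, 12474, 13785 and 12668 UMIs in the young libraries and 7955, 7008.5 and 5986 UMIs in the old libraries.

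The first comparison asked which cell classes made up the tissue at each age. Plasma cells, the antibody-secreting end stage of the B lineage, rose from 1 cell in the 4 young libraries to 113 cells in the 3 old libraries. Their share of kept cells was 0.00556% ± 0.0111 (SD, n = 4) in the young mice and 0.590% ± 0.119 (SD, n = 3) in the old mice. The log2 fold change was 6.24 (SE 1.10; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00011). Schwann cells, the glia of peripheral nerves, fell from 1.41% ± 1.27 (SD, n = 4) to 0.187% ± 0.0651 (SD, n = 3), a log2 fold change of -2.90 (SE 0.91; edgeR adjusted p = 0.0293). Young replicates 2, 3 and 4 had no plasma cell, which allows shares of up to 0.0538%, 0.107% and 0.0538%, and the lowest old share was 0.498% (95% exact Clopper-Pearson interval 0.334% to 0.715%).

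T cells, neutrophils, monocytes and B cells had higher mean shares in the old mice without passing the test. T cells made up 5.54% ± 4.23 (SD, n = 4) of the young and 16.9% ± 1.74 (SD, n = 3) of the old cells, with every old library above every young one (log2 fold change 1.61, edgeR adjusted p = 0.137). Neutrophils made up 0.189% ± 0.0941 (SD, n = 4) and 0.765% ± 0.247 (SD, n = 3), with edgeR adjusted p = 0.0888. Monocytes made up 1.43% ± 0.243 (SD, n = 4) and 4.11% ± 2.23 (SD, n = 3), with edgeR adjusted p = 0.137. B cells made up 2.72% ± 2.34 (SD, n = 4) and 9.25% ± 10.3 (SD, n = 3), and old replicate 3 alone had 21.1%. Adipose progenitors, the fibroblast-like cells that give rise to adipocytes, made up 39.3% ± 11.2 (SD, n = 4) and 23.8% ± 6.58 (SD, n = 3), with edgeR adjusted p = 0.485. Mean macrophage shares were 13.1% and 15.98%, and mean endothelial shares 12.4% and 12.2%.

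In the 2-sided exact permutation test over the 35 splits of the 7 libraries, plasma cells, neutrophils and monocytes each reached p = 0.0286, the smallest p the design allows. Schwann and T cells reached a permutation p = 0.0571. None of the 16 classes passed after adjustment of these permutation p-values, which were 0.152 for the lowest. With 35 splits and 16 classes, a class at the smallest p passes only when many others reach it too. The adjusted permutation result therefore says little against a single class. The Schwann call was lost without old replicate 1, 2 or 3 in turn, with edgeR adjusted p up to 0.132. Progenitor sub-clusters were grouped by fixed markers into interstitial (30.9% ± 7.42, SD, n = 4, of young and 19.2% ± 7.21, SD, n = 3, of old progenitors), committed preadipocyte (54.3% and 71.9%) and regulatory cells (12.6% and 6.22%). Of these 3 subclasses, 0 passed in edgeR (1 at an unadjusted p under 0.05) or in the permutation test.

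**Figure D1:**
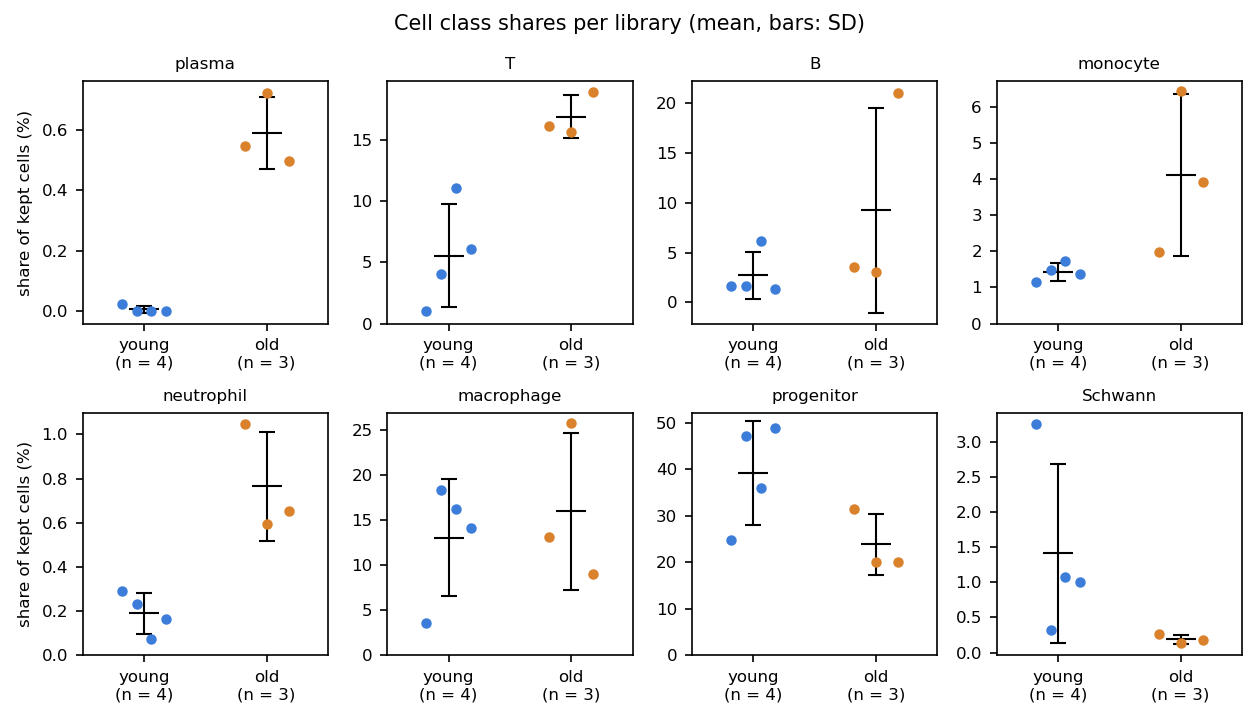
Share of kept cells (%, vertical axis) of 8 cell classes in the 4 young and 3 old libraries; each point is a library, the horizontal bar is the mean and the whiskers are the SD. Plasma cells lie at 0.0223% or below in each young library and at 0.498% or above in each old library.

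In adipose progenitors, H19, an imprinted non-coding RNA of embryonic growth, fell from 172 ± 134 (SD, n = 4) to 4.79 ± 2.31 (SD, n = 3) CPM (library-scaled counts) in the summed progenitor counts, and Cthrc1, a secreted protein made by matrix-producing fibroblasts, fell from 129 ± 22.7 to 15.0 ± 2.16 CPM. Col1a1, a chain of type I collagen, fell from 8906 ± 4285 to 2516 ± 534 CPM and Col3a1, the type III collagen chain, from 19611 ± 6456 to 7453 ± 628 CPM. Genes that rose included the secreted chemokine Cxcl14 (101 ± 28.1 to 736 ± 407 CPM) and Dmkn, an epithelial secreted protein (8.39 ± 3.97 to 87.2 ± 10.3 CPM). Cdkn2a, which encodes the cell cycle inhibitor p16 and is used as a mark of senescence, rose from a low level of 0.796 ± 0.404 to 5.60 ± 3.63 CPM.

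Of 13969 genes tested in progenitors, 90 rose and 165 fell with age (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of the 255, 77 were over 10 times higher in another class, 47 of them among the 90 that rose, so free RNA was not excluded for these. The summed counts held 11185900 to 55397000 UMIs per library. All 255 genes separated the ages without overlap, as did 17.5% of all genes tested. The log2 fold changes were -5.18 for H19 (SE 0.89, edgeR adjusted p = 0.0257), -3.12 for Cthrc1 (SE 0.20, edgeR adjusted p = 0.0013) and -1.82 for Col1a1 (SE 0.37, edgeR adjusted p = 0.0439). They were 2.86 for Cxcl14 (SE 0.36, edgeR adjusted p = 0.0107), 3.37 for Dmkn (SE 0.35, edgeR adjusted p = 0.00534) and 2.78 for Cdkn2a (SE 0.55, edgeR adjusted p = 0.0414). On build mm10, H19 (ENSMUSG00000000031) lies on chromosome 7 at 142575529 to 142578143. Cxcl14 (ENSMUSG00000021508) lies on chromosome 13 at 56288643 to 56296551 and Cdkn2a (ENSMUSG00000044303) on chromosome 4 at 89274471 to 89294653.

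The other large decreases were in Mest and Zim1, both imprinted genes, Postn, a matrix protein of remodelling tissue (5502 ± 1555 to 987 ± 105 CPM), Lrrc15, a surface protein of myofibroblasts, Cpz, a carboxypeptidase, Frem1, a basement membrane protein, the glutamate receptor Gria1 and the death receptor Tnfrsf21. Their log2 fold changes ran from -3.29 for Gria1 to -2.10 for Tnfrsf21. The other large increases were in Krtdap, the homeobox gene Meox1, the receptor Mrgprg, the tubulin Tuba4a, the tight junction gene Cldn15, Thsd7a, the antisense RNA Atcayos and Csprs. Their log2 fold changes ran from 2.14 for Thsd7a to 4.33 for Atcayos. Csprs shares sequence with a family of near-identical copies and Atcayos overlaps its sense gene, so their counts are uncertain. Cdkn1a, which encodes the cell cycle inhibitor p21, had 111 ± 79.7 (SD, n = 4) and 388 ± 197 (SD, n = 3) CPM and did not pass in edgeR (adjusted p = 0.141). Nor did Dpp4 and Pi16, marks of interstitial progenitors (adjusted p = 0.53 and 0.496), Icam1 (0.296) or the adipogenic regulator Pparg (0.426).

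**Figure D2:**
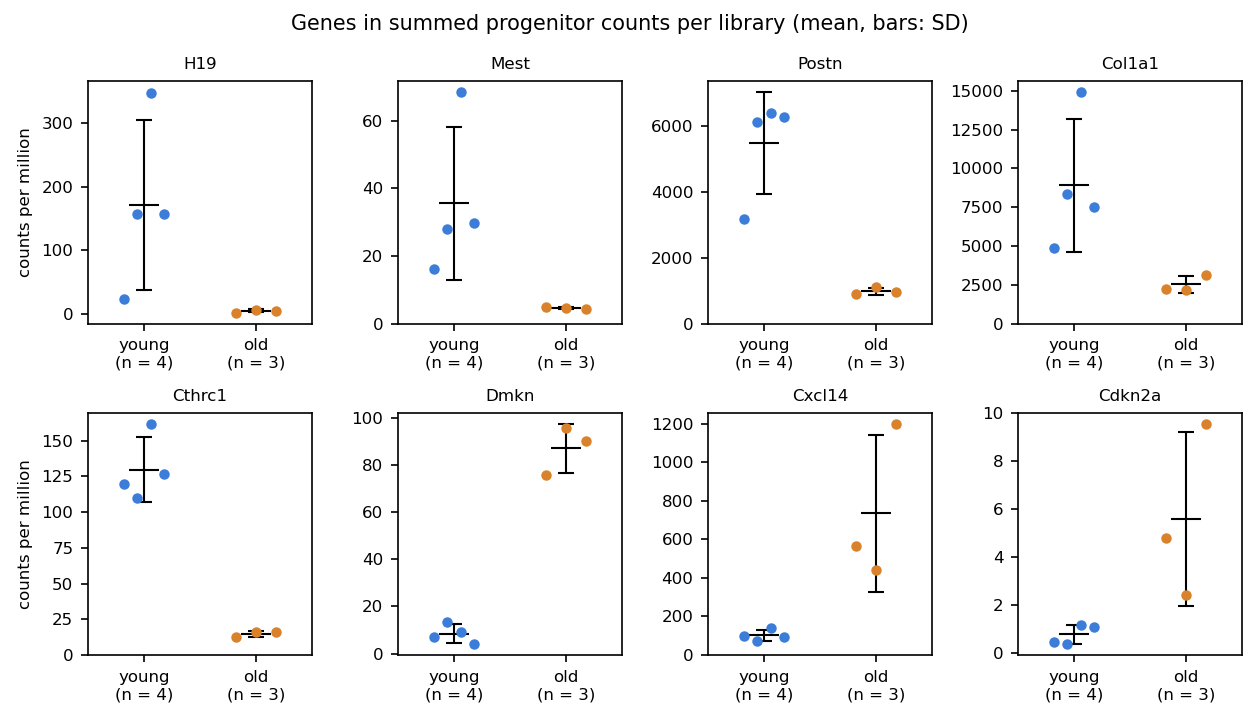
CPM (vertical axis, from 0 or just below) of 8 genes in the summed progenitor counts of the 4 young and 3 old libraries; each point is a library, the horizontal bar is the mean and the whiskers are the SD. H19, Mest, Postn, Col1a1 and Cthrc1 are lower in each old library than in each young one, and Dmkn, Cxcl14 and Cdkn2a are higher.

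Among gene lists fixed before the data were examined, the fibrillar collagen and matrix list shifted downward in progenitors. Of 24 members, 16 were lower and 8 higher, 5 fell over all genes tested and 8 adjusted over the list alone, and 0 rose (camera adjusted p = 0.000115; adjusted p = 0.611 with an estimated correlation). They included Fn1, the cell adhesion protein fibronectin, with a log2 fold change of -1.78, and Col1a2, with -1.62. In old replicate 3, Col1a2 and Col3a1 lay far below the other 6 libraries in 6 of 7 classes. Progenitors were the exception. There Col1a2 had 3246 unscaled CPM against at least 4253 in the other libraries, and Col3a1 6622 against at least 7000. The heat shock list shifted upward (camera adjusted p = 0.00244; adjusted p = 0.666 with an estimated correlation), with 0 of 12 members passing over all genes tested and 1 adjusted over the list alone. Its strongest member, the endoplasmic reticulum chaperone Hspa5, had 667 ± 238 (SD, n = 4) and 1661 ± 72.3 (SD, n = 3) CPM and edgeR adjusted p = 0.0536. Young replicate 1 stood apart in this list, with a mean log2 level of 6.86 against 7.87 to 8.19 in the other young and 8.21 to 8.63 in the old libraries. Without it camera adjusted p was 0.0376.

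The immediate early list, which tissue dissociation induces, shifted upward in progenitors (camera adjusted p = 0.0397; adjusted p = 0.827 with an estimated correlation) with 0 of 19 members passing, 0 adjusted over the list alone. It turned downward without young replicate 1 (camera adjusted p = 0.934), in which 12 genes, among them Atf3, Cxcl1 and Il6, lay far below the other 6 libraries in most classes. Lists made of other cells' genes shifted upward too: resident macrophage (11 members, camera adjusted p = 0.0089; adjusted p = 0.623 with an estimated correlation), MHC class II (7 members, camera adjusted p = 0.00983; adjusted p = 0.66 with an estimated correlation) and cytotoxic T (8 members, camera adjusted p = 0.0346; adjusted p = 0.594 with an estimated correlation). No member of these 3 lists passed over all genes tested. Adjusted over the list alone, 1 cytotoxic member rose. Of their members, 9, 7 and 7 were over 10 times higher in another class. MHC class I (15 members, camera adjusted p = 0.0261; adjusted p = 0.816 with an estimated correlation) and complement (14 members, camera adjusted p = 0.0376; adjusted p = 0.611 with an estimated correlation) shifted upward with 0 members passing over all genes tested, and 0 and 3 adjusted over the list alone. Of their members, 3 and 5 were over 10 times higher in another class, C1qa and C1qb of complement among them. MHC class I lost its call without young replicate 3, young replicate 4 or old replicate 3 (camera adjusted p up to 0.511) and complement without young replicate 3 or old replicate 2 (up to 0.24). MHC class II lost its call without old replicate 3 (0.16), cytotoxic T without young replicate 4 or old replicate 2 (up to 0.0623) and resident macrophage without old replicate 2 (0.105). The immediate early list also lost its call without old replicate 3. The senescence list did not pass (camera adjusted p = 0.0818), with 2 of 16 members higher and 0 lower over all genes tested.

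Cluster 1, led by H19, Lrrc15 and Postn, held 33.1% ± 16.8 (SD, n = 4) of young and 3.12% ± 1.44 (SD, n = 3) of old progenitors. Cluster 4, led by Smoc2 and Cxcl14, held 2.35% ± 0.918 and 44.2% ± 2.27. Clusters 6 and 10 held means of 20.2% and 2.75% of young and 3.07% and 21.4% of old progenitors. The 255 gene changes are not separated from this makeup. Without batch integration, some sub-clusters came almost wholly from 1 library. Sub-cluster 1 had 1240 of 1284 cells from young replicate 2, and sub-cluster 9 had 512 of 522 from old replicate 3. The count of 255 genes was 453 without young replicate 1, 124 without young replicate 3, 95 without young replicate 4, 31 without old replicate 1 and 45 without old replicate 2. Of 29 named genes that passed, 13 passed under every left-out library, among them Cthrc1, Cxcl14, Dmkn, Krtdap, Mrgprg, Thsd7a, Zim1 and Postn. Cdkn2a lost its call under each of the 7. Col1a1 and Col3a1 lost theirs under 6 of the 7, with edgeR adjusted p up to 0.193 and 0.18. H19 lost its call without young replicate 4 or any of the 3 old libraries in turn, with edgeR adjusted p up to 0.114.

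In macrophages, Rnase2a, a secreted ribonuclease of the eosinophil-associated family, rose from 1.77 ± 1.30 (SD, n = 4) to 69.3 ± 41.9 (SD, n = 3) CPM, a log2 fold change of 5.52 (SE 0.57, edgeR adjusted p = 0.00654). Complement component C2, which forms part of the classical C3 convertase, fell from 32.6 ± 1.90 to 5.53 ± 0.851 CPM (log2 fold change -2.53, SE 0.19, edgeR adjusted p = 0.000973). The scavenger receptor Colec12 fell by 1.92 on the log2 scale and Pank1, which starts coenzyme A synthesis, fell by 1.36, while the homeobox gene Barx2 rose by 3.73. Trem2, Lyve1, Cd74 and Cdkn1a, fixed beforehand, did not pass in edgeR (adjusted p = 0.969, 1.00, 0.973 and 1.00). Cdkn2a had 1.16 ± 0.395 (SD, n = 4) and 4.97 ± 1.94 (SD, n = 3) CPM (adjusted p = 0.189). C2 (ENSMUSG00000024371) lies on chromosome 17 at 34862604 to 34898265.

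Of 11695 genes tested in macrophages, 8 rose and 9 fell, and 9 of these 17 were over 10 times higher in another class, so free RNA of that class was not excluded. One of these was Gpnmb, a lysosomal protein of lipid-laden macrophages, at 2.66 ± 1.43 (SD, n = 4) and 50.5 ± 38.7 (SD, n = 3) CPM (edgeR adjusted p = 0.026). It was higher in monocytes. The lipid-associated macrophage list shifted upward with Gpnmb as the 1 of 14 members that rose and 3 adjusted over the list alone (camera adjusted p = 0.000187; adjusted p = 0.503 with an estimated correlation). The complement list shifted downward with C2 as its 1 member that fell and 2 adjusted over the list alone (camera adjusted p = 0.00239; adjusted p = 0.503 with an estimated correlation). Of its 14 members, 6 were over 10 times higher in another class. The proliferation list shifted upward (18 of 19 members higher, 0 passing, 0 adjusted over the list alone, camera adjusted p = 4.71e-06, adjusted p = 0.611 with an estimated correlation). Its mean log2 level was low in young replicates 1 and 2 (3.56 and 4.10). In young replicates 3 and 4 (5.42 and 5.11) it lay close to the old libraries (5.15 to 5.51). The interferon response list shifted downward (23 of 25 members lower, 0 passing, 0 adjusted over the list alone, camera adjusted p = 5.44e-07, adjusted p = 0.594 with an estimated correlation). Its mean log2 level was 5.48 and 5.29 in old replicates 1 and 3. Old replicate 2 (6.23) lay within the young range (5.81 to 6.52). Ifi27l2a, an interferon-induced gene, had 2005 ± 545 (SD, n = 4) and 1103 ± 372 (SD, n = 3) CPM (edgeR adjusted p = 0.551).

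Further lists passed the camera test in macrophages with 0 members passing over all genes tested. MHC class I shifted downward (14 of 15 members lower, 0 adjusted over the list alone, adjusted p = 8.15e-05; adjusted p = 0.611 with an estimated correlation). So did the resident macrophage list (9 of 12 lower, 0 adjusted over the list alone, adjusted p = 0.029; adjusted p = 0.503 with an estimated correlation). Heat shock (12 of 12 higher, adjusted p = 0.0366; adjusted p = 0.806 with an estimated correlation), oxidative phosphorylation (21 of 25 higher, adjusted p = 0.0418; adjusted p = 0.827 with an estimated correlation) and the immediate early list (11 of 19 higher, adjusted p = 0.0493; adjusted p = 0.842 with an estimated correlation) shifted upward, each with 0 members adjusted over the list alone. Without young replicate 1 heat shock and the immediate early list turned downward, and without old replicate 3 oxidative phosphorylation did. Mature adipocyte genes (8 members, 1 higher adjusted over the list alone, adjusted p = 7.58e-05; adjusted p = 0.503 with an estimated correlation) and endothelial adhesion genes (10 members, 1 higher adjusted over the list alone, adjusted p = 0.00302; adjusted p = 0.559 with an estimated correlation) shifted upward. Of each list, 8 members were over 10 times higher in another class. Fibrillar collagen (22 members, 11 lower adjusted over the list alone, adjusted p = 1.02e-12; adjusted p = 0.552 with an estimated correlation) and basement membrane genes (12 members, 1 lower adjusted over the list alone, adjusted p = 0.00826; adjusted p = 0.721 with an estimated correlation) shifted downward. All 22 and all 12 were over 10 times higher in another class. Without old replicate 3, basement membrane (camera adjusted p = 0.489), heat shock, oxidative phosphorylation, the immediate early and the resident macrophage list lost their calls. Without old replicate 2, endothelial adhesion (0.095) and resident macrophage lost theirs, and without old replicate 1 the immediate early list. Without young replicate 3, basement membrane and resident macrophage lost theirs, and without young replicate 2 or 4 oxidative phosphorylation. The count of 17 genes was 2 without young replicate 3, 4 without young replicate 4, 5, 10 and 6 without old replicate 1, 2 or 3. Of 9 named genes that passed, C2 and Itm2a passed under every left-out library, and Itm2a was over 10 times higher in another class.

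In T cells of old mice, Gzmk, a granzyme of effector memory CD8 T cells, rose from 7.60 ± 8.85 (SD, n = 4) to 112 ± 32.3 (SD, n = 3) CPM. Eomes, a transcription factor of effector and memory CD8 T cells, rose from 19.3 ± 7.18 to 191 ± 63.5 CPM. The inhibitory receptor gene Lag3 rose from 1.99 ± 1.89 to 34.9 ± 15.1 CPM, and the interleukin 10 receptor gene Il10ra from 15.4 ± 8.77 to 58.6 ± 8.95 CPM. The log2 fold changes were 4.78 for Gzmk (SE 0.51, edgeR adjusted p = 0.0029), 3.25 for Eomes (SE 0.33, edgeR adjusted p = 0.0029), 3.90 for Lag3 (SE 0.47, edgeR adjusted p = 0.00639) and 2.24 for Il10ra (SE 0.32, edgeR adjusted p = 0.0205). The checkpoint gene Pdcd1 had 8.11 ± 3.21 (SD, n = 4) and 39.9 ± 25.6 (SD, n = 3) CPM and did not pass (edgeR adjusted p = 0.071).

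Of 9815 genes tested in T cells, 31 rose and 3 fell, and 11 of the 34 were over 10 times higher in another class, 10 of them among the 31. The others of the largest increases were AA467197, Camk2n1, Baiap3, Sdcbp2, the drug efflux pump Abcb1a and Dtx4, with log2 fold changes from 1.81 for Dtx4 to 4.68 for AA467197, and Galnt10, a glycosyltransferase, fell by 1.21. Sostdc1, a secreted BMP and Wnt antagonist, had 0 UMIs in young T cells and 32.8 ± 12.6 (SD, n = 3) CPM in old ones, at least 72.8-fold higher against a floor of 3 UMIs over the young group (edgeR adjusted p = 0.00443). Sostdc1 was also over 10 times higher in Schwann cells, whose share was higher in the young libraries. Gzmk (ENSMUSG00000042385) lies on chromosome 13 at 113171608 to 113225908 and Eomes (ENSMUSG00000032446) on chromosome 9 at 118478212 to 118486132.

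The cytotoxic and effector memory list shifted upward in T cells, with Gzmk and Eomes as the 2 of 16 members that rose and 3 adjusted over the list alone (camera adjusted p = 1.15e-07; adjusted p = 0.503 with an estimated correlation). The T exhaustion list shifted upward with Lag3 as the 1 of 8 members that rose and 4 adjusted over the list alone (camera adjusted p = 5.53e-06; adjusted p = 0.461 with an estimated correlation). The naive T list shifted downward, with 9 of 10 members lower, 0 passing over all genes tested and 1 adjusted over the list alone (camera adjusted p = 0.00382, adjusted p = 0.666 with an estimated correlation). Its mean log2 level was high in young replicates 3 and 4 (8.91 and 8.72). Old replicate 3 (7.62) lay above young replicates 1 and 2 (6.79 and 7.35). All 82 cytosolic ribosomal protein genes had negative fold changes, with 0 passing and 0 adjusted over the list alone (camera adjusted p = 1.48e-11, adjusted p = 0.701 with an estimated correlation). Their mean log2 level in old replicate 3 (11.76) also lay above young replicates 1 and 2 (11.46 and 11.5). The interferon response list shifted upward, with 21 of 24 members higher, 0 passing and 1 adjusted over the list alone (camera adjusted p = 0.000102; adjusted p = 0.552 with an estimated correlation).

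Further lists passed the camera test in T cells. Immediate early genes shifted upward (1 of 19 members, Ier3, rose, 1 adjusted over the list alone, adjusted p = 8.15e-05; adjusted p = 0.623 with an estimated correlation). Ier3 was over 10 times higher in another class. The list's mean log2 level was 6.85 in young replicate 1 and at least 8.09 elsewhere, and young replicate 2 (8.81) lay above old replicates 1 and 2. Without young replicate 1 camera adjusted p was 0.0184. MHC class I (0 of 15 passing, 1 adjusted over the list alone, adjusted p = 0.00414; adjusted p = 0.721 with an estimated correlation) and the age-associated B list (0 of 11 passing, 0 adjusted over the list alone, adjusted p = 0.00104; adjusted p = 0.552 with an estimated correlation) shifted upward too. Oxidative phosphorylation shifted downward (23 of 25 members lower, 0 passing, 0 adjusted over the list alone, adjusted p = 0.000822, adjusted p = 0.738 with an estimated correlation). Its mean log2 level was low in old replicates 1 and 2 (7.02 and 6.95). In old replicate 3 (7.51) it lay above the young range (7.33 to 7.44). Adipogenic (0 of 15 passing, 1 higher adjusted over the list alone, adjusted p = 0.00225; adjusted p = 0.503 with an estimated correlation) and lipid-associated macrophage genes (0 of 12 passing, 1 higher adjusted over the list alone, adjusted p = 0.00865; adjusted p = 0.611 with an estimated correlation) shifted upward. Of their members, 14 and 11 were over 10 times higher in another class. Fibrillar collagen genes shifted downward (0 of 20 passing, 5 lower adjusted over the list alone, adjusted p = 5.36e-09; adjusted p = 0.611 with an estimated correlation). All 20 were over 10 times higher in another class. MHC class I lost its call without old replicate 3 (camera adjusted p = 0.293), naive T without old replicate 2 (0.0529), oxidative phosphorylation without old replicate 1 or 2 (up to 0.106) and lipid-associated macrophage without young replicate 3 or old replicate 2 (up to 0.0737).

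The 3 T cell clusters held different shares. Cluster 7, led by CD8 effector genes with Gzmk and Eomes, held 21.99% ± 14.9 (SD, n = 4) of young and 43.7% ± 12.5 (SD, n = 3) of old T cells. Cluster 11, with naive genes, held 53.1% ± 29.3 and 18.2% ± 14.5, with 20% and 37.1% in young replicates 1 and 2 and 80.9% and 74.5% in young replicates 3 and 4. Cluster 8, led by CD4 T cell genes, held 24.9% ± 14.6 and 38.1% ± 15.98. Of the 3 T cell clusters it scored highest for CD4, regulatory and gamma delta markers alike, the last on 2 measured genes. It may therefore mix kinds of T cells. The summed T cell counts held 265342 to 6307690 UMIs per library. The count of 34 genes was 19 without young replicate 1, 66 without young replicate 2, 4 without young replicate 3, 4 without young replicate 4, 11 without old replicate 1 and 119 without old replicate 3. Of 15 named genes that passed, Gzmk, Eomes, Lag3 and Sostdc1 passed under every left-out library.

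**Figure D3:**
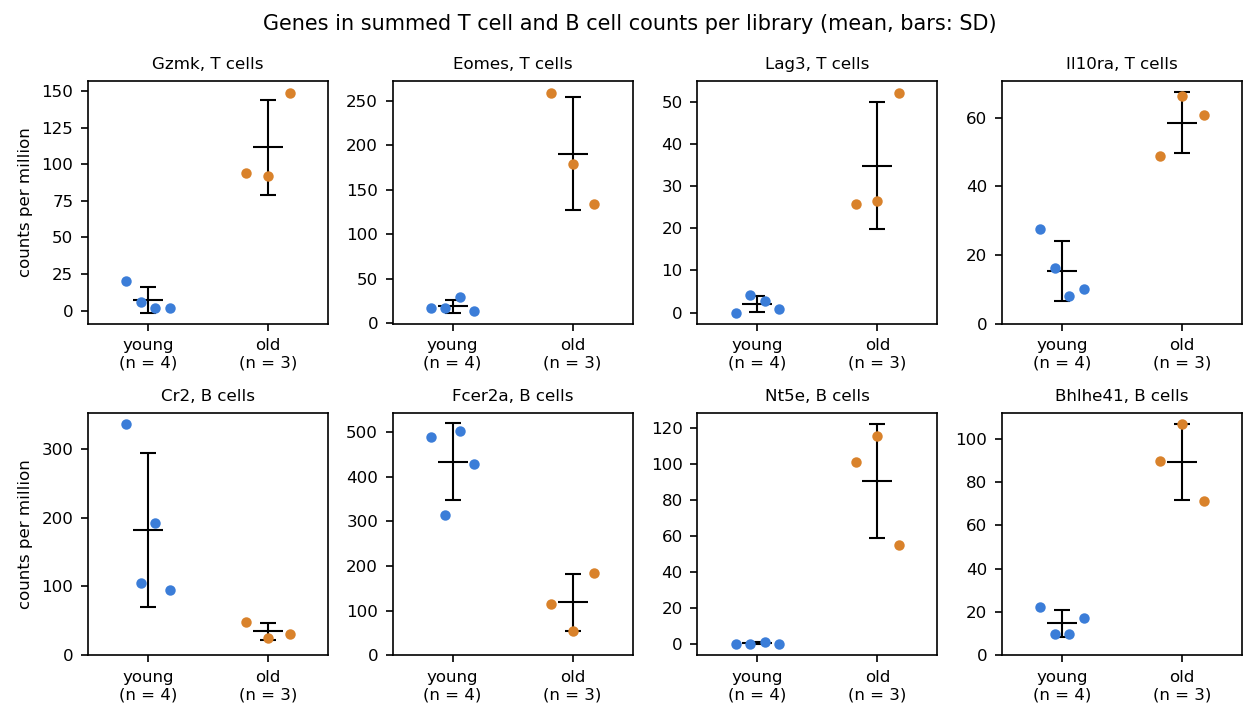
CPM (vertical axis, from 0 or just below) of 4 genes in summed T cell counts and 4 in summed B cell counts of the 4 young and 3 old libraries; each point is a library, the horizontal bar is the mean and the whiskers are the SD. Gzmk, Eomes, Lag3 and Il10ra are higher in each old library than in each young one in T cells, as are Nt5e and Bhlhe41 in B cells, where Cr2 and Fcer2a are lower.

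In B cells of old mice, Cr2 and Fcer2a, which encode the complement receptor CD21 and the IgE receptor CD23 of follicular B cells, fell from 182 ± 112 (SD, n = 4) to 34.4 ± 12.2 (SD, n = 3) CPM and from 434 ± 86.1 to 118 ± 64.7 CPM. Bhlhe41, a transcription factor of B-1a cells, rose from 14.7 ± 6.15 to 89.3 ± 17.7 CPM. Nt5e, which encodes the ecto-nucleotidase CD73, rose from 0.245 ± 0.491 to 90.6 ± 31.9 CPM. The log2 fold changes were -2.41 for Cr2 (SE 0.41, edgeR adjusted p = 0.00807), -1.86 for Fcer2a (SE 0.35, edgeR adjusted p = 0.0125) and 2.72 for Bhlhe41 (SE 0.33, edgeR adjusted p = 0.000713). Young B cells held 1 UMI of Nt5e and old ones 584, a depth-adjusted ratio of 149 (95% counting interval 26.7 to 5915; edgeR adjusted p = 1.42e-05). Tbx21, which encodes T-bet, the regulator of age-associated B cells, had 1 UMI in young and 99 in old B cells, a ratio of 25.3 (95% counting interval 4.44 to 1011; edgeR adjusted p = 0.0159), and was over 10 times higher in another class.

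Of 7569 genes tested in B cells, 61 rose and 19 fell. The other large increases included Spn, the surface protein CD43 of B-1 and activated B cells, the transcription factors Sox5 and Nfil3, the lipid receptor Gpr55, Plscr1, Wipf3 and Dnm3. Dnm3 had 0 UMIs in young B cells and 255 in old ones, at least 21.8-fold higher against a floor of 3 UMIs over the young group. The other large decreases were in Icosl, the ligand of the T cell co-stimulator ICOS, the cannabinoid receptor Cnr2, Pgap1, Brwd1, Rapgef4, Cpm and BC094916, with log2 fold changes from -2.24 for BC094916 to -1.29 for Cnr2. Of the 80 genes, 34 were over 10 times higher in another class, among them Postn, Col1a1 and Col3a1, which fell. Cr2 (ENSMUSG00000026616) lies on chromosome 1 at 195136811 to 195176716 and Nt5e (ENSMUSG00000032420) on chromosome 9 at 88327197 to 88372092.

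All 9 measured members of the age-associated B list had positive fold changes, 4 rose over all genes tested (Nt5e, Tbx21, Fas and Apoe) and 9 adjusted over the list alone (camera adjusted p = 4.18e-12; adjusted p = 0.461 with an estimated correlation). Of the 9, 6 were over 10 times higher in another class. The MHC class I list shifted upward, with H2-Q7 as the 1 of 15 members that rose and 2 adjusted over the list alone (camera adjusted p = 3.81e-06; adjusted p = 0.461 with an estimated correlation). Ribosomal protein genes shifted downward (62 of 81 lower, 0 passing, 0 adjusted over the list alone, camera adjusted p = 0.0199; adjusted p = 0.886 with an estimated correlation) but turned upward without old replicate 2. Fibrillar collagen genes shifted downward (5 of 17 fell, 8 adjusted over the list alone, camera adjusted p = 2.07e-18; adjusted p = 0.503 with an estimated correlation). So did basement membrane genes (0 of 7 passing, 0 adjusted over the list alone, camera adjusted p = 0.0446; adjusted p = 0.682 with an estimated correlation), which turned upward without old replicate 3. Lipid-associated macrophage genes shifted upward (1 of 10, Lgals3, rose, 1 adjusted over the list alone, camera adjusted p = 0.00264; adjusted p = 0.618 with an estimated correlation). All 17, 7 and 10 members of these last lists were over 10 times higher in another class. The ribosomal list also lost its call without young replicate 1 or old replicate 1, and the basement membrane list without young replicate 1, 2 or 3.

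All B cells came from 1 cluster, and the young libraries held only 74, 92, 174 and 76 of them. The cluster was not divided further, so the 80 gene changes are not separated from its makeup of B cell kinds. The summed counts held 325409 to 5659760 UMIs per library. The count of 80 genes was 26 without young replicate 3, 50 without young replicate 4, 53 without old replicate 2 and 250 without old replicate 3. Of 32 named genes that passed, 15 passed under every left-out library, among them Cr2, Icosl, Bhlhe41, Nt5e, Nfil3 and Plscr1. Fcer2a lost its call without young replicate 3 or old replicate 1. Tbx21 could be tested in only 3 of the 7 and lost its call in 1, without young replicate 2. Sox5 and Gpr55 could be tested in 4 and Fas in 5, and each lost its call in 2.

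In endothelial cells, Ubd, a ubiquitin-like protein induced by inflammatory cytokines, rose from 19.6 ± 8.33 (SD, n = 4) to 132 ± 24.5 (SD, n = 3) CPM (log2 fold change 2.83, SE 0.27, edgeR adjusted p = 0.0058). Brip1, a DNA repair helicase, rose from 1.45 ± 0.555 to 24.0 ± 10.1 CPM (log2 fold change 4.12, SE 0.40, edgeR adjusted p = 0.0058). Lamb1, a laminin chain of the basement membrane, fell from 80.9 ± 18.1 to 28.6 ± 5.87 CPM (log2 fold change -1.50, SE 0.22, edgeR adjusted p = 0.0346). Gpr1, Chchd10, the fatty acid desaturase Fads3 and Msmp also rose, by 2.26, 1.68, 1.52 and 1.06 on the log2 scale. Itm2a fell by 2.07, the hyaluronan-binding Itih5 by 1.82 and Ncoa7 by 1.37 on the log2 scale. The adhesion molecule gene Vcam1 had 35.4 ± 14.5 (SD, n = 4) and 11.7 ± 1.57 (SD, n = 3) CPM and did not pass (edgeR adjusted p = 0.124), nor did Cdkn1a (edgeR adjusted p = 0.994). Cdkn2a was too low to test, with 4 UMIs in young replicate 2, 0 in the other young libraries and 18, 9 and 7 in the old ones.

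Of 11727 genes tested in endothelial cells, 10 rose and 7 fell, and 1 of the 17 was over 10 times higher in another class. The basement membrane list shifted downward, with Lamb1 as the 1 of 12 members that fell and 3 adjusted over the list alone (camera adjusted p = 4.9e-05; adjusted p = 0.503 with an estimated correlation). The interferon response list shifted downward (20 of 25 lower, 0 passing, 6 adjusted over the list alone, camera adjusted p = 3.01e-06; adjusted p = 0.552 with an estimated correlation). So did endothelial activation and adhesion genes (9 of 13 lower, 0 passing, 6 adjusted over the list alone, camera adjusted p = 0.00244; adjusted p = 0.461 with an estimated correlation). Ribosomal protein genes shifted downward (82 of 83 lower, 0 passing, 0 adjusted over the list alone, camera adjusted p = 9.7e-17; adjusted p = 0.611 with an estimated correlation). Fibrillar collagen genes shifted downward (0 of 23 passing, 10 adjusted over the list alone, camera adjusted p = 3.81e-06; adjusted p = 0.611 with an estimated correlation). Of the 23, 21 were over 10 times higher in another class. MHC class II genes shifted upward (0 of 6 passing, 5 adjusted over the list alone, camera adjusted p = 8.15e-05; adjusted p = 0.552 with an estimated correlation). Cytotoxic T (0 of 8 passing, 3 adjusted over the list alone, camera adjusted p = 0.000338; adjusted p = 0.537 with an estimated correlation) and resident macrophage genes (0 of 11 passing, 1 adjusted over the list alone, camera adjusted p = 0.00296; adjusted p = 0.611 with an estimated correlation) shifted upward. Of these 3 lists, 6, 7 and 9 members were over 10 times higher in another class. The resident macrophage list lost its call without young replicate 1 or old replicate 2 (camera adjusted p up to 0.0746).

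Clusters 16 and 23 held most endothelial cells of young replicate 1 (53.6% and 27.5%), while cluster 2 held 69.2% ± 5.27 (SD, n = 3) of the old endothelial cells and 40.4% ± 28.5 (SD, n = 4) of the young. Cluster 23, led by Plvap and the adhesion genes Selp and Vwf, held 13.1% ± 9.88 (SD, n = 4) of young and 2.92% ± 0.774 (SD, n = 3) of old endothelial cells, lower in each old library. Selp and Vwf belong to the endothelial activation and adhesion list, so its downward shift is not separated from this makeup. The count of 17 genes was 35 without young replicate 1, 26 without young replicate 2, 6 and 4 without young replicates 3 and 4, 5 and 11 without old replicates 1 and 2 and 48 without old replicate 3. Of 11 named genes that passed, Ubd and Brip1 passed under every left-out library. Ubd (ENSMUSG00000035186) lies on chromosome 17 at 37193892 to 37196095.

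**Figure D4:**
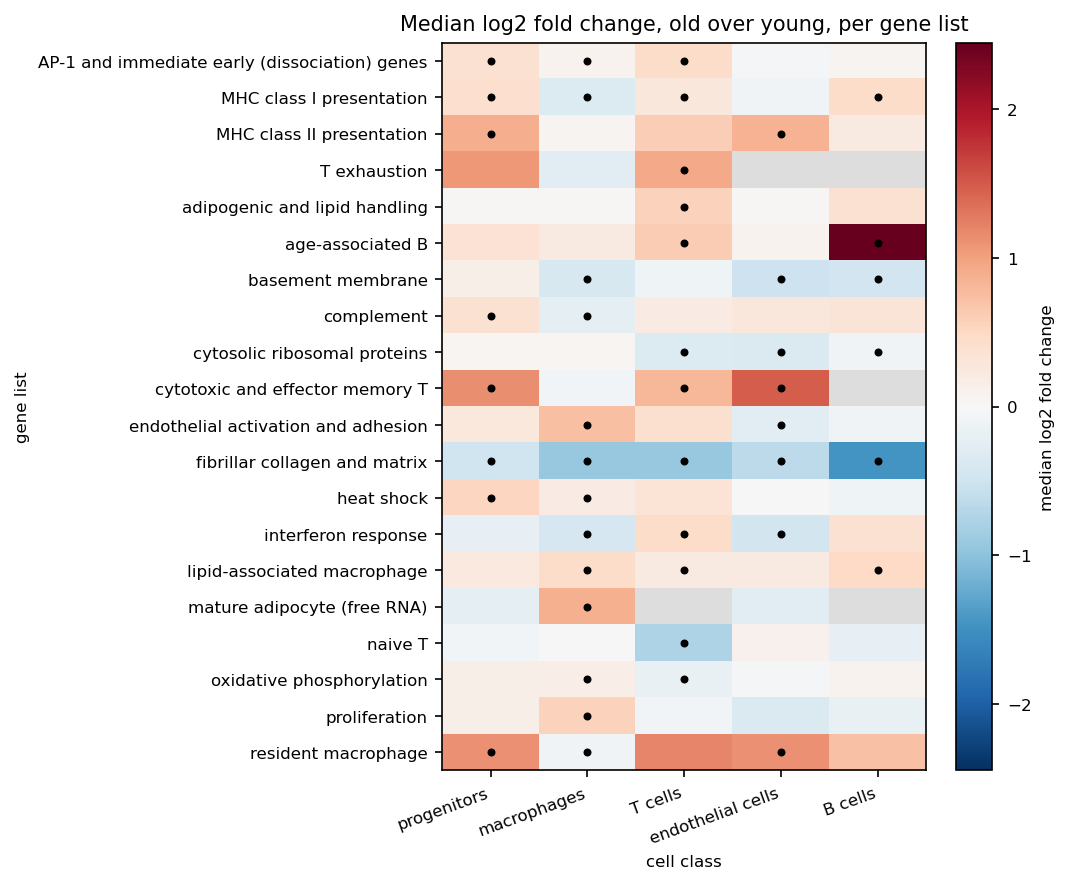
Median log2 fold change, old over young (colour), of the members of each gene list (vertical axis) in the 5 main cell classes (horizontal axis); grey marks lists with fewer than 5 members tested, and dots mark a camera adjusted p under 0.05 with the preset correlation. The age-associated B list in B cells has the largest median, 2.45, and fibrillar collagen genes have negative medians in all 5 classes.

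Across the 5 classes, 47 of the list tests passed camera with its preset correlation, and 0 passed with an estimated correlation. The fry test, which asks whether a list's genes move 1 way on balance, passed 0.

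The other classes held 871 changed genes, of which 822 were in luminal epithelial cells of the mammary gland that lies in this fat pad (515 rose, 307 fell; edgeR). Of the 822, 179 were over 10 times higher in another class, 151 of them among the 515. Csn1s1, a milk casein, rose there from 4.19 ± 4.24 (SD, n = 4) to 3454 ± 2930 (SD, n = 3) CPM (edgeR adjusted p = 0.0107) and Amtn, a secreted mineralisation protein, from 0.0425 ± 0.0849 to 48.8 ± 29.2 CPM. Dmbt1, a mucosal scavenger protein, fell from 239 ± 141 to 2.68 ± 2.49 CPM and Col8a1 from 102 ± 26.9 to 1.52 ± 1.56 CPM. The secretory cluster 24 held 15.2% ± 7.49 (SD, n = 4) of young and 77.4% ± 20.3 (SD, n = 3) of old luminal cells. Cluster 18, led by hormone-sensing genes, held 75.2% ± 10.3 and 10.2% ± 7.40. Within cluster 24, with 2 young and 3 old libraries, 641 of the 736 luminal genes that could be tested kept their direction. Their median log2 fold change was 0.52 against 1.79 in the whole class. The genes were picked from sums that include these same cells, which favours a kept direction. The 2 young libraries, young replicates 1 and 4, held 134 and 20 cells of the cluster. Basal epithelial cells had 35 changed genes, among them Zfp296 and Dapk2, which rose, and Them5 and Sostdc1, which fell, and 6 of the 35 were over 10 times higher in another class. Monocytes had 10, among them Arg1, the enzyme arginase 1 (5.83 ± 10.7, SD, n = 4, to 124 ± 64.9, SD, n = 3, CPM; edgeR adjusted p = 0.0302), and Ctsk, a collagen-degrading protease. Of the 10, the 7 that fell, Col1a1, Col3a1 and Postn among them, were all over 10 times higher in another class. Dendritic cells had 3 (Jchain, Postn and Ly6d), all over 10 times higher in another class. Mural cells had Caprin2 alone, and natural killer and mast cells had 0 in edgeR (368 and 238 at an unadjusted p under 0.05). The count of 871 was 1339 without young replicate 1, 380, 378 and 296 without young replicates 2, 3 and 4, 42 without old replicate 1, 1517 without old replicate 2 and 494 without old replicate 3.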

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

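All tests of explanations in this part were chosen after the results they address were seen.

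Among 115 values tested in the 4 young libraries, 12 had 1 library far from the other 3; groups of 3 were not tested. In 5 of the 12 the other 3 libraries were at 0, which fixes the outcome at 1.00, and 1 further value was 0 throughout. This leaves 7 of 109, near the 1 in 20 that chance gives. The figures that follow are the gap to the nearest library over the group's range. B cells made up 6.22% of young replicate 3 and at most 1.65% of the others (0.941). The only young plasma cell was in young replicate 1 (1.00). Postn in progenitors was 3176 CPM in young replicate 1 and at least 6140 CPM in the others (0.915), and Thsd7a was 13.8 CPM in young replicate 4 and at most 10.5 CPM in the others (0.885). Cdkn2a in macrophages was highest in young replicate 3, at 1.75 CPM (0.857). AA467197 in T cells was 17.1 CPM in young replicate 1 and at most 2.55 CPM in the others (0.892), and Arg1 in monocytes was 21.9 CPM there and at most 1.39 CPM in the others (0.936). Lamb1 in endothelial cells was 108 CPM in young replicate 4 and at most 75.2 CPM in the others (0.862). Nt5e and Wipf3 in B cells, Tbx21 in B cells and Amtn in luminal cells each had UMIs in 1 young library alone (1.00 each).

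Some gene lists moved in opposite directions in different classes, and the difference between the classes was tested with an exact permutation over 35 splits in 10 comparisons. In 6 of these p was 0.0286, the smallest the splits allow (exact permutation, adjusted p = 0.0476). The 10 comparisons were formed only from lists that had passed camera in opposite directions in these same libraries. Their p-values are therefore not independent of that selection, and the adjustment covers only the 10. The log2 fold change of the MHC class I list was higher than in macrophages by 0.68 in progenitors, by 0.63 in T cells and by 0.76 in B cells. Interferon response was higher by 0.89 in T cells than in macrophages, and oxidative phosphorylation by 0.35 in macrophages than in T cells. Without members over 10 times higher in another class, these 5 kept p = 0.0286 (exact permutation). The sixth, complement, was higher by 0.82 in progenitors than in macrophages, but only 4 of its 14 members were left when such genes, C1qa and C1qb among them, were taken out, too few to test. The MHC class I calls within a class were lost without young replicate 3, young replicate 4 or old replicate 3 in progenitors and without old replicate 3 in T cells. The other 4 comparisons did not pass: interferon response in T against endothelial cells (0.74, exact permutation adjusted p = 0.204), endothelial adhesion in macrophages against endothelial cells (0.68, adjusted p = 0.214), and resident macrophage in progenitors (0.89) and endothelial cells (0.73) against macrophages (both adjusted p = 0.286).

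Of the unnamed clusters, 5 were not mostly doublets and entered no comparison. Cluster 13 held 1023 cells with mural genes (Rgs5, Kcnj8) beside the endothelial gene Plvap. Cluster 27 held 349 cells led by Cd163l1, Cxcr6 and Icos, cluster 28 held 316 cells led by H2-M2 and Dnase1l3, cluster 29 held 261 cells led by cell cycle genes such as Top2a and Mki67, and cluster 31 held 193 cells led by haemoglobin genes, 187 of them in old replicates 1 and 2.

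Plasma cells were nearly absent in young mice, and Jchain, the joining chain of secreted antibodies, rose in 6 classes of the old mice. Free RNA of plasma and B cells is a candidate explanation for the Jchain calls outside the B lineage. In each old library the Jchain to Mzb1 UMI ratio outside plasma and B cells lay within a log2 departure of 0.96 of that inside. The share of cells with a Jchain UMI in old replicate 2 was 16.4% in progenitors (13073 median UMIs). It was 16.2% in macrophages (5510.5) and 12.7% in T cells (4754.5). The UMIs per positive cell were uneven. In old replicate 1, 75 T cells held 310 and 152 progenitors held 171, and in old replicate 2, 289 macrophages held 800. Doublets with plasma cells that remained would keep the same ratio, so the ratio cannot tell them apart from free RNA. More lymph node tissue of unchanged makeup in the old dissections stays open for the plasma cells: old replicate 3 had 1.82 plasma cells per 100 B and naive T cells, against a limit of 3.61 in young replicate 1, although old replicates 1 and 2 had 8.74 and 19.1. The exact permutation p was 0.114 on the log2 scale with counts under 3 raised to that limit, the first test run, and 0.0286 on the observed values, a test changed to after that result was seen. Of the 35 splits, 2 gave at least the 2 changed classes of the real one, with 3 as the highest other (young replicates 1, 3 and 4 against the rest), so chance cannot be excluded for that count; age stays open, untested.

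The T cell genes changed while the clusters shifted. The genes kept their direction within clusters in 25 of 26 tested in cluster 7, 22 of 22 in cluster 8 and 9 of 9 in cluster 11. The lower quartiles of the signed log2 fold changes were 1.60, 0.93 and 0.73. This cannot decide whether shares of the 3 T cell clusters are the whole cause for the set. The genes were picked from sums of these same cells, which favours a kept direction, and 11 of the 34 may be free RNA. Inside cluster 7, Gzmk and Eomes rose by 3.89 and 2.40 on the log2 scale (edgeR adjusted p = 0.000923 and 0.0158), which argues against shares as the whole cause for them. Lag3, Il10ra, Abcb1a and Pdcd1 did not pass there. How large a part the shares have cannot be told apart: the medians within clusters were 2.28, 1.34 and 1.53 against 2.75 in the whole class, and 1.34 misses the bound written first, over 0.5 of the whole-class value in each, after which the quartile bound was chosen. Finer states inside a cluster stay open, untested. Of the 35 splits, 2 gave at least the 34 genes of the real one, with 37 for young replicates 1, 3 and 4 against the rest, so chance cannot be excluded for the count; age stays open, untested.

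C130026I21Rik, AC168977.1 and Csprs, members of a family of near-identical copies on chromosome 1 and unplaced sequence, rose in old progenitors (C130026I21Rik 1.72 ± 0.918, SD, n = 4, to 43.0 ± 14.2, SD, n = 3, CPM; edgeR adjusted p = 0.00208). AC168977.1 also rose in B cells (2 young and 681 old UMIs, edgeR adjusted p = 6.15e-06) and macrophages (edgeR adjusted p = 0.0148). The log2 fold change of C130026I21Rik, here from means of log2 of unscaled CPM plus 1, was larger by 4.14 in progenitors than in dendritic cells (exact permutation p = 0.0286). These had the largest and smallest folds of the classes compared, and B cells had 3.06. A variant that acts alike in every cell type is argued against for C130026I21Rik in progenitors and dendritic cells only. Such a variant cannot be told apart for AC168977.1 (difference 1.70, exact permutation p = 0.0286, on 1 young UMI in dendritic cells) and Csprs (1.21, exact permutation p = 0.0571). Reads of 1 transcript split between the copies cannot be told apart either, since the AC168977.1 UMIs per C130026I21Rik UMI were 4.38-fold higher in old progenitors (exact permutation p = 0.0857) on few young UMIs. The origin of the mice cannot be told apart from age: the neighbouring gene Sp110 had 0.358 CPM in the progenitors of old replicate 3 and at least 20.2 CPM in the other 6 libraries, so the locus varied within 1 age too.

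For the other results, 1 of 35 splits (the real one) gave as many genes in progenitors (255, highest other 8), macrophages (17, highest other 6), endothelial cells (17, highest other 6), B cells (80, highest other 18) and the other classes (871, highest other 138). This is the smallest share that 35 splits allow, and it was not adjusted over the results. Merging similar libraries left 13, 4, 1 and 44 genes in progenitors, macrophages, endothelial cells and B cells. Chance is thus argued against but not excluded there. For gene lists, 17 of the 35 splits gave at least the 47 of the real one (highest other 59), so chance cannot be excluded. For progenitor subclasses the real split gave 0 (highest other 1). Every split reaches 0 whatever the data, so the splits test nothing there.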

How the results depend on the processing

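Merging similar libraries and leaving out low-UMI clusters were chosen after seeing the data. Of the single genes, lists and shares under alternatives, 3211 kept their direction and side of the threshold, 473 were no longer past it, 91 newly passed and 6 reversed; the cause was not tested. The reversals, with the largest other moves of the same list, were AP-1 and immediate early (dissociation) genes in progenitors (camera adjusted p = 0.934; 0.00176 without young replicate 4), AP-1 and immediate early (dissociation) genes in macrophages (0.0237; 0.000814 without young replicate 4, 0.52 without old replicate 3) and heat shock in macrophages (0.99; 0.000478 without young replicate 4) without young replicate 1, cytosolic ribosomal proteins in B cells without old replicate 2 (0.934; 1.33e-24 without old replicate 3), and oxidative phosphorylation in macrophages (0.251; 0.00044 without old replicate 1) and basement membrane in B cells (0.638; 0.00893 without old replicate 1) without old replicate 3.

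Leaving out 1 library at a time gave 31 to 453 genes in progenitors (255 with all), 2 to 23 in macrophages (17), 4 to 119 in T cells (34), 4 to 48 in endothelial cells (17), 26 to 250 in B cells (80), 42 to 1517 in the other classes (871), 1 to 3 cell classes (2), 0 to 1 progenitor subclasses (0; 1 without young replicate 2) and 46 to 55 lists (47). DESeq2 called 983 genes in progenitors (including all 255), 89 in macrophages (all 17), 77 in T cells (32 of 34), 220 in endothelial cells (all 17), 130 in B cells (77 of 80) and 1804 in the other classes. No expression filter gave 67, 374, 160 and 323 genes in macrophages, T cells, endothelial cells and B cells. Clustering at resolution 2 gave 5, 22 and 9 in macrophages, T cells and endothelial cells. The stricter cell filter gave 19 in T cells and 27 in endothelial cells. Merged libraries gave 13 genes in progenitors (8 higher, 5 lower), 4 in macrophages, 12 in T cells, 1 in endothelial cells, 44 in B cells and 1 cell class. Without low-UMI clusters, macrophages had 31 genes and 1 class changed. Of class shares, 6 passed with TMM factors, 0 in the exact permutation test, and 1 each at resolution 2 and among cells other than lymphocytes. The permutation test could pass a class only with many others at its smallest p. Of lists, 0 passed with an estimated correlation and 0 by fry.

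The replicate numbers do not pair the samples: same-numbered libraries' progenitor deviations correlated at -0.0184, 0.0326 and 0.0236. With the replicate block (replicates 1 to 3) there were 96 genes in progenitors (77 shared), 9 in macrophages, 55 in T cells, 0 in endothelial cells, 162 in B cells, 1 cell class and 2 progenitor subclasses. The stricter filter gave no value for B cells, with fewer than 2 young libraries of 20 cells, and doublets kept was not run for progenitor subclasses. RLE size factors and thinning to equal mean UMIs per cell moved no count of genes in the 5 main classes by over 1.5 times. They were not run for the other classes. The thinning left the numbers of cells as they were, so the summed counts still differed in size between libraries. Depth limits genes with few young UMIs, such as Nt5e and Tbx21 in B cells.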

Other observations

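The test in this part was chosen after the result was seen, and Peg3 and Mirg had been seen among genes leading progenitor clusters before the list was drawn up, so it is not independent of them. Several imprinted genes, which are expressed from 1 parental copy and many of which regulate fetal growth, were lower in old progenitors besides H19, Mest and Zim1. H19 led progenitor cluster 1, which held 33.1% of young and 3.12% of old progenitors on average. No test was run within progenitor clusters, so these decreases are not separated from that cluster's share. Peg3 fell from 277 ± 61.3 (SD, n = 4) to 94.0 ± 7.85 (SD, n = 3) CPM (edgeR adjusted p = 0.0139), the long non-coding RNA Meg3 from 1396 ± 580 to 395 ± 97.5 CPM (edgeR adjusted p = 0.0402), the cell cycle inhibitor Cdkn1c from 395 ± 120 to 133 ± 45.1 CPM (edgeR adjusted p = 0.0405), the amino acid transporter Slc38a4 from 29.7 ± 7.88 to 7.41 ± 1.25 CPM (edgeR adjusted p = 0.00954) and Usp29 from 1.14 ± 0.0446 to 0.0728 ± 0.0639 CPM (edgeR adjusted p = 0.016). As a group, the 21 other tested members of a list of imprinted genes had a mean log2 CPM difference of -0.74 in old progenitors, with 17 lower (5 passing) and 4 higher (0 passing), and an exact permutation p of 0.0571 over 35 splits, so the group as a whole did not pass.

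Single libraries stood apart across cell classes. In young replicate 1, 12 genes lay far below the other 6 libraries in most classes measured, among them Atf3 (88.7 CPM in progenitors, against at least 520 CPM elsewhere) and Cxcl1 (46.6 against at least 512 CPM), and 8 lay above, among them the epithelial genes Epcam and Krt18. In old replicate 3, 6 lay below, among them Sp110 and Gm42418, and in old replicate 1, Hbb-bs, S100a8 and S100a9 lay above. Ltf, a milk protein, rose in luminal cells (105 ± 77.0, SD, n = 4, to 4443 ± 3028, SD, n = 3, CPM; edgeR adjusted p = 0.0179), macrophages and progenitors, and 8.72% of macrophages in old replicate 1 (7305.5 median UMIs) held an Ltf UMI beside 82.5% of luminal cells (18066 median UMIs).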
